A study of Mus musculus with 24 samples.

How the data were processed

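Total RNA from 24 mouse aortic homogenates was, per the labels, made into messenger RNA libraries with a spin-column RNA kit and a commercial mRNA library kit. The samples fall into 6 groups of 4 by treatment (Ang II or sham) and months after the 2-week infusion (2, 4 or 6). The submitters' processing notes name FastQC, cutadapt, STAR, featureCounts, DESeq2 and build mm10. Versions, annotation release, strand setting and the handling of reads shared by genes are not given in the sources used here. The authors deposited a table of whole-number read counts for 37606 Ensembl genes in 24 libraries. They also deposited tables of Ang II against sham at each time, with the same counts, a log2 fold change, its standard error, a p-value and an adjusted p-value per gene, and a fold change as a ratio. Each full table by the authors was checked to hold only genes whose largest count is at least 5. That is not their whole rule, since genes left out had counts up to 544, 196 and 2831 at 2, 4 and 6 months. Each shorter table was checked to hold those with an adjusted p under 0.05 and an absolute log2 fold change of at least 1. All 24 count columns were matched to a sample by name. Of the gene IDs, 23514 were given symbols from the deposited tables and 14015 from the reference annotation, and 77 had none.

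Counts were analysed in R 4.3.3 with edgeR 4.0.16, which was the tool of each comparison. Genes were kept by filterByExpr (minimum count 10, minimum total 15), libraries were scaled by TMM, and the quasi-likelihood F test (glmQLFit, glmQLFTest) was used with Benjamini-Hochberg adjustment at 0.05. Ang II was compared with sham within each time (8 libraries). Over all 24 libraries, the interaction of treatment and time was tested, and the average Ang II effect with time as a block. Sham libraries (12) were compared over the 3 times and pairwise. SE of a log2 fold change is its size over the square root of its F. CPM in the comparisons are TMM-normalised over the libraries of that comparison, and those of single libraries, list sums and plots over all 24. The depth per library ranged from 19.16 to 58.68 (in 1e6 counts), and at 6 months at least 31.75% of it was mitochondrial. In simulated data with planted changes edgeR recovered 5.97%, 49.3% and 87.9% of changes of 1.5-, 2- and 4-fold at 2 months, 11.9%, 59.7% and 90.9% at 4 months and 0%, 8.96% and 77.3% at 6 months, and false calls were 7 of 102, 3 of 111 and 3 of 60.

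Gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 3, preset correlation 0.01, Benjamini-Hochberg over lists with at least 5 measured members), then with an estimated correlation and with fry, which asks whether a list's genes move one way. With the estimated correlation no list passed in any comparison. Fry passed 5, 5 and 0 lists at 2, 4 and 6 months, 0 for the average, and 6, 14 and 19 for sham at 4 against 2, 6 against 2 and 6 against 4 months. Camera passed 18 of 32, 17 of 32, 14 of 33, 19 of 33, 20 of 32, 8 of 32 and 8 of 32. The 34 lists were: collagens, elastic fibre, matricellular, matrix proteases, contractile smooth muscle, osteochondrogenic, fibroblast, endothelial, lymphatic and mesothelial, macrophage and monocyte, T and NK cell, B and plasma cell, neutrophil and mast cell, thymocyte, antigen presentation, cytokines and chemokines, interferon stimulated, TAM, renin angiotensin aldosterone, oxidant and antioxidant, brown adipocyte, general adipocyte, fatty acid synthesis, oxidative phosphorylation, skeletal muscle, cardiac muscle, Schwann and neuronal, erythroid, circadian clock, immediate early, heat shock and ER stress, proliferation, senescence, and genes expressed from the sex chromosomes, of which too few members were measured for a test. These lists, the comparisons, the filters, the thresholds, the other settings to be tried and the rule for named genes were chosen before the data were examined.

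The rule named, for the Ang II effect at each time and on average, up to 10 called genes with the largest rise and 10 with the largest fall among those with a mean CPM of at least 1, up to 4 called members per list, and always the 5 TAM genes, Agtr1a, Col1a1, Col3a1, Eln and Acta2. Where fewer than 10 genes passed, the 5 highest and 5 lowest by signed p were added. For sham over time it named 5 genes each way per contrast and up to 3 per list, of which the text gives part and sensitivity counts cover all. For the interaction it named the 10 smallest p. Predicted genes (Gm or Rik symbols) and IDs without a symbol were counted but not named. A few genes that this rule picked are not reported here, and none was put in their place.

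Other settings were DESeq2 size factors in edgeR, DESeq2 1.42.0, no low-count filter, a mean count of at least 5 and limma voom with library quality weights. Further ones were an adipocyte covariate, an absolute log2 fold change of at least 1, replicate numbers as a block, that block with the adipocyte covariate, all 24 libraries in 1 fit, and leaving out each library. Chosen after the data were seen were lists of airway, hepatocyte, adrenal cortex, squamous, kidney tubule and cartilage genes, covariates for airway, squamous epithelium and contractile smooth muscle, fits without the libraries highest in such transcripts or in ribosomal RNA, without chromosome M and ribosomal RNA genes, and without the 6-month libraries. Replicates of a group were checked not to be copies of each other (Pearson r from 0.916 to 0.984). Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.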

Results

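RNA from 24 homogenates of mouse aorta was sequenced, by the labels as messenger RNA. The wild-type mice had received angiotensin II (Ang II), the peptide hormone that constricts arteries and raises blood pressure, or vehicle (sham) by osmotic minipump for 2 weeks. Aortas were taken 2, 4 or 6 months later, so there were 6 groups with 4 libraries each. The series concerns Axl, a receptor tyrosine kinase of the TAM family (Tyro3, Axl and Mertk), in organ damage that follows hypertension. Total counts of replicates 1 to 4, in units of 1e6, were 24.35, 22.28, 23.41 and 21.21 in sham and 27.09, 35.13, 19.38 and 24.50 in Ang II aortas at 2 months. At 4 months they were 22.37, 19.98, 21.03 and 24.90 in sham and 19.92, 21.25, 21.24 and 19.16 in Ang II aortas. At 6 months they were 45.32, 43.88, 46.79 and 53.27 in sham and 40.96, 44.57, 58.68 and 37.64 in Ang II aortas. The labels do not say whether replicates are separate animals, so the p-values measure only the spread between these samples, which may be technical. Errors of means are SD over 4 libraries per group, and errors of log2 fold changes are SE. Y-linked transcripts were present in every library (Ddx3y, an RNA helicase gene of the Y chromosome, at 46.4 to 95.1 CPM, reads per 1e6 counts), and Xist, the RNA that silences an X chromosome in females, lay between 0 and 0.729 CPM.

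The 6-month libraries were of another kind than the earlier ones. Transcripts of mitochondrial chromosome M took 31.75% to 59.31% of the counts in the 8 libraries at 6 months, against 7.72% to 14.28% at 2 months and 10.07% to 16.32% at 4 months. Rn7sk, the small nuclear RNA that holds back transcription elongation and carries no poly(A) tail, lay at 2182 to 3771 CPM at 6 months and at 2.05 to 15.38 CPM before. Mt-Rnr2, the large mitochondrial ribosomal RNA, took 21.5% to 38.44% of the counts at 6 months. Once chromosome M and ribosomal RNA genes were set aside, 12.61 to 35.1 (in 1e6) counts remained per library at 6 months, 17.03 to 32.14 at 2 months and 16.69 to 22.35 at 4 months. The first principal component held 61.3% of the variance. Time and kind of library are therefore confounded between 6 months and the earlier times, but not within a time.

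**Figure D1:**
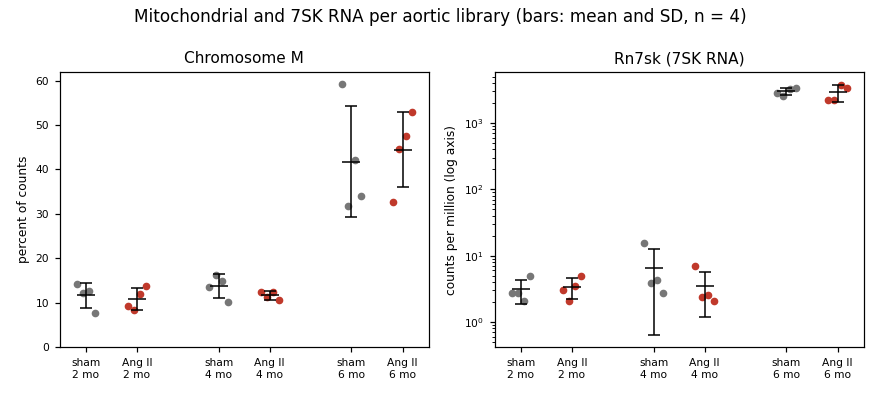
Share of counts from chromosome M (percent, linear axis) and Rn7sk (plain CPM, log axis) in each of the 24 libraries by group. Points are libraries, horizontal lines means and bars SD (n = 4); Rn7sk is at 2182 to 3771 CPM in the 6-month libraries and at 2.05 to 15.38 CPM in the others.

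The comparison at 2 months asks which transcripts differed from sham 2 months after a hypertensive episode. Smooth muscle and elastic fibre transcripts were lower in Ang II aortas, while immediate early and macrophage transcripts were higher. Acta2, smooth muscle alpha-actin (ENSMUSG00000035783.8, chromosome 19, 34241090 to 34255336, build mm10), fell from 2543 ± 1069 to 445 ± 255 CPM (log2 fold change -2.51, SE 0.433, edgeR adjusted p = 0.0251). Eln, which encodes the elastin precursor (ENSMUSG00000029675.12, chromosome 5, 134702593 to 134747323), fell from 992 ± 419 to 144 ± 70.2 CPM (log2 fold change -2.79, SE 0.414, edgeR adjusted p = 0.0152). Apold1, an early response gene of endothelial cells (ENSMUSG00000090698.2, chromosome 6, 134981718 to 134986836), rose 12.8-fold, from 4.65 ± 1.08 to 59.6 ± 27.6 CPM (log2 fold change 3.68, SE 0.347, edgeR adjusted p = 0.00470). Cd68, a lysosomal glycoprotein of macrophages (ENSMUSG00000018774.13, chromosome 11, 69664213 to 69666153), rose from 11.99 ± 4.84 to 34.02 ± 6.17 CPM (log2 fold change 1.51, SE 0.266, edgeR adjusted p = 0.0280).

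The contractile smooth muscle list fell at 2 months: 12 of 20 measured members fell over all genes tested and 15 adjusted over the list alone, none rose, and the median log2 fold change was -1.67 (camera adjusted p = 2.65e-19, adjusted p = 0.0745 with an estimated correlation). Besides Acta2, Itga8, an integrin subunit of smooth muscle, fell from 285 ± 75.5 to 30.1 ± 18.8 CPM and Myl9, a myosin light chain, from 708 ± 190.3 to 163 ± 70.2 CPM. The actin-binding genes Smtn and Lmod1 changed by -1.53 and -1.95 on the log2 scale (edgeR adjusted p from 0.00589 for Smtn to 0.0148 for Myl9). The elastic fibre and crosslinking list fell with 6 of 23 members, and 13 adjusted over the list alone (median -0.63; camera adjusted p = 3.71e-11, adjusted p = 0.200 with an estimated correlation). Its members Mfap4, a microfibril glycoprotein, Ltbp1 and Ltbp4, which hold latent TGF-beta in the matrix, changed by -2.32, -1.73 and -0.73 (edgeR adjusted p = 0.00820, 0.00820 and 0.0248). Of 16 collagens, 2 fell over all genes and 5 adjusted over the list alone (median -0.35; camera adjusted p = 2.06e-05, adjusted p = 0.349 with an estimated correlation): Col1a2 went from 536 ± 66.6 to 346 ± 11.9 CPM and Col6a3 changed by -0.57 (edgeR adjusted p = 0.0292 and 0.0367). Col1a1, the other chain of type I collagen, did not pass (log2 fold change -0.64, SE 0.140, edgeR adjusted p = 0.0685; 4 of 4 Ang II libraries below every sham library), nor did Col3a1 (-0.14, edgeR adjusted p = 0.878). The matricellular and TGF-beta response list fell with 4 of 17 members, and with 8 lower and 2 higher adjusted over the list alone (median -0.39; camera adjusted p = 3.25e-05, adjusted p = 0.200 with an estimated correlation). Its members Bgn, the proteoglycan biglycan, Postn, periostin, Tnc, tenascin C, and Tgfb2 changed by -1.73, -1.29, -1.25 and -1.16 (edgeR adjusted p from 0.00955 for Bgn to 0.0240 for Tnc). The osteochondrogenic list fell with 0 of 10 members passing edgeR over all genes and 3 adjusted over the list alone (median -0.47; camera adjusted p = 9.86e-04, adjusted p = 0.200 with an estimated correlation).

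Among the largest falls at 2 months were genes outside these lists. Wif1 (ENSMUSG00000020218.11, chromosome 10, 121033960 to 121100650) and Sost, which both block Wnt signals, changed by -3.77 and -3.46, and the Wnt ligand gene Wnt16 by -2.89. Npnt, a matrix ligand of integrins, fell from 143 ± 36.9 to 17.4 ± 5.79 CPM (log2 fold change -3.03, SE 0.283, edgeR adjusted p = 0.00470). The phosphatase gene Ppef1, the coiled-coil gene Ccdc42, the serotonin receptor gene Htr1b and the secreted glycoprotein gene Scube3 changed by -3.60, -3.11, -2.97 and -2.96, with edgeR adjusted p from 0.0118 for Htr1b to 0.0487 for Ccdc42. Summed contractile transcripts were 7624, 6048, 5649 and 8879 CPM in sham replicates 1 to 4 and 2787, 2174, 3344 and 2089.7 CPM in Ang II replicates at 2 months. In all 16 libraries at 4 and 6 months that sum lay between 1698 and 5022 CPM, below every sham library at 2 months. Airway epithelium transcripts, from a list chosen after the data were seen, summed to 16.4, 2.57, 9327 and 739 CPM in the sham and 2433, 1223, 93.4 and 12.99 CPM in the Ang II libraries.

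**Figure D2:**
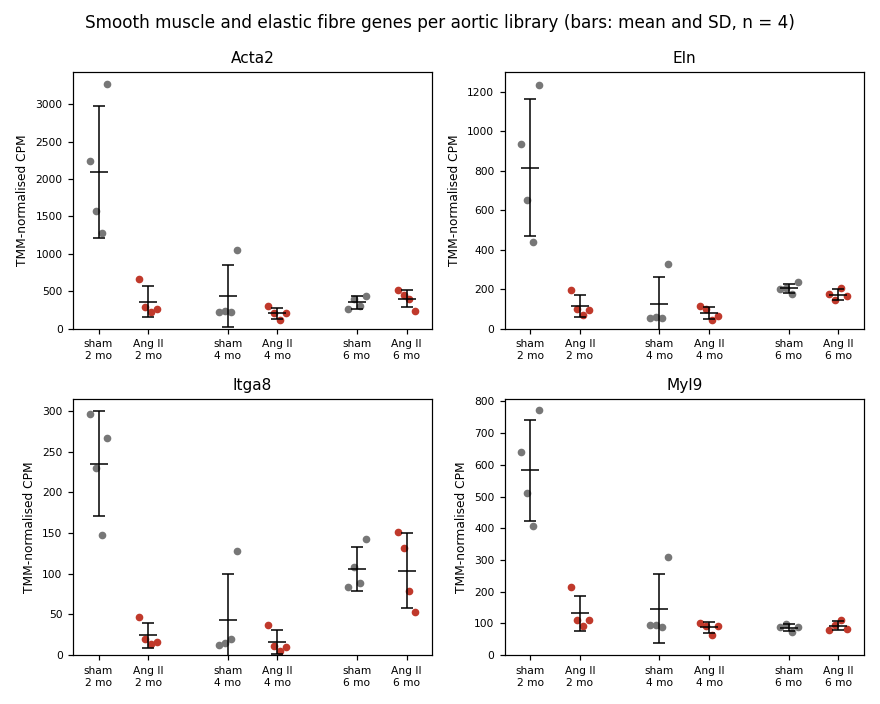
Acta2, Eln, Itga8 and Myl9 in CPM (TMM-normalised over all 24 libraries, linear axes) by group. Points are libraries, horizontal lines means and bars SD (n = 4); the sham SD bar of Eln at 4 months runs below 0 and ends at the axis. At 2 months Acta2 lies between 226 and 664 CPM in Ang II libraries, below every sham library.

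The immediate early list rose at 2 months with 5 of 19 members, and 10 adjusted over the list alone (median 1.28; camera adjusted p = 1.57e-09, adjusted p = 0.200 with an estimated correlation). Nr4a1, an orphan nuclear receptor induced within minutes of a stimulus (ENSMUSG00000023034.6, chromosome 15, 101266846 to 101274792), rose from 42.5 ± 13.2 to 363 ± 164 CPM (log2 fold change 3.09, SE 0.373, edgeR adjusted p = 0.00820). Atf3, a stress-induced transcription factor, rose 5.05-fold, and Klf2 and Klf4, transcription factors that respond to blood flow, by 1.28 and 1.24 on the log2 scale (edgeR adjusted p = 0.0110, 0.0106 and 0.0161). Other large rises were Slc25a25, a mitochondrial carrier, at 2.61, Irf4, an interferon regulatory factor, at 2.33, the protease gene Adamts4 at 2.23, the kinase gene Sik1 at 2.16, Arc at 2.06 and the insulin receptor substrate gene Irs2 at 1.98. Their edgeR adjusted p lay between 0.00820 for Slc25a25 and 0.0487 for Arc. The summed immediate early level was 2394, 1503, 885 and 976 CPM in Ang II replicates 1 to 4 and 492, 715, 509 and 642 CPM in sham.

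The macrophage and monocyte list rose at 2 months: 3 of 18 members rose over all genes, 9 adjusted over the list alone, and all 18 had fold changes above 0 (median 0.59; camera adjusted p = 2.76e-09, adjusted p = 0.200 with an estimated correlation). Trem2, a lipid-sensing receptor of macrophages (ENSMUSG00000023992.14, chromosome 17, 48346401 to 48354147), rose from 2.45 ± 0.481 to 6.87 ± 1.92 CPM, and Adgre1, the F4/80 antigen gene, from 12.01 ± 2.06 to 23.7 ± 3.55 CPM (edgeR adjusted p = 0.0240 and 0.0202). Of 15 cytokines and chemokines, Ccl8, which draws monocytes, passed at 2.11, and 1 adjusted over the list alone (median 0.43; camera adjusted p = 0.00854, adjusted p = 0.200 with an estimated correlation). Further lists rose with 0 members passing edgeR over all genes or adjusted over the list alone. They were B and plasma cells (median 1.41; camera adjusted p = 2.06e-05), T and NK cells (0.42; camera adjusted p = 0.00302), antigen presentation (0.50; camera adjusted p = 3.17e-06) and proliferation (0.94; camera adjusted p = 9.86e-04). In this order these lists had adjusted p = 0.486, 0.683, 0.394 and 0.660 with an estimated correlation. Summed B cell transcripts ranged from 286 to 1381 CPM in sham and from 624 to 2754 CPM in Ang II libraries. Skeletal muscle also rose, with 0 members passing (median 1.25; camera adjusted p = 0.0369). So did the general adipocyte list, in which the activin receptor gene Acvr1c passed at 0.71 (median 0.21; camera adjusted p = 0.00182). In order the lists had adjusted p = 0.707 and 0.486 with an estimated correlation. Single libraries decided some of these calls. Skeletal muscle was not called without sham replicates 1 or 3 (camera adjusted p = 0.290 and 0.167) or Ang II replicates 2, 3 or 4 (0.185, 0.657 and 0.0892). T and NK cells were not called without sham replicate 4 (0.122) or Ang II replicate 2 (0.143), nor proliferation without Ang II replicate 2 (0.0969).

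Further lists fell at 2 months. The erythroid list fell with 0 members passing over all genes and 5 of 6 adjusted over the list alone (median -1.45; camera adjusted p = 6.31e-05, adjusted p = 0.220 with an estimated correlation). In the circadian clock list the repressor gene Bhlhe41 fell (-1.06) and 8 of 18 fell adjusted over the list alone (median -0.45; camera adjusted p = 6.31e-05, adjusted p = 0.157 with an estimated correlation). The oxidative phosphorylation list fell with 0 of 20 members passing (median -0.11; camera adjusted p = 0.0196, adjusted p = 0.707 with an estimated correlation). It was not called without sham replicates 1 or 3 (camera adjusted p = 0.162 and 0.119) or Ang II replicates 1 or 2 (0.0771 and 0.963). Of the lists that did not pass, matrix proteases and inhibitors came nearest (camera adjusted p = 0.0774; Adamts4 rose and Timp3, an inhibitor of these proteases, fell by 0.58 on the log2 scale). Single members passed in other uncalled lists: Cldn5, an endothelial tight junction gene, at 1.40, Nox4, a superoxide-producing oxidase gene, at -2.27, Prdm16, a brown fat regulator, at -0.93, Gdf15, a stress cytokine, at 1.84, and the stress genes Dnajb1 and Atf4 at 0.49 and 0.51. The brown adipocyte, interferon stimulated, neutrophil and mast cell, oxidant and antioxidant, Schwann and neuronal, senescence, endothelial, heat shock, renin angiotensin aldosterone, fatty acid synthesis, cardiac muscle, fibroblast and lymphatic lists had camera adjusted p from 0.117 to 0.913. Among these the signs of median, mean and test differed for renin angiotensin aldosterone, fatty acid synthesis, cardiac muscle, fibroblast and lymphatic.

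The TAM list fell at 2 months with 1 of 5 members over all genes and 1 adjusted over the list alone (median -0.40; camera adjusted p = 0.0218, adjusted p = 0.220 with an estimated correlation). The list was not called with the adipocyte covariate (camera adjusted p = 0.0792) or without Ang II replicate 3 (0.0652). The member that passed was Mertk, the TAM receptor that serves uptake of dying cells (ENSMUSG00000014361.5, chromosome 2, 128698956 to 128802894), from 38.1 ± 6.14 to 22.7 ± 2.77 CPM (log2 fold change -0.74, SE 0.139, edgeR adjusted p = 0.0346). Axl (ENSMUSG00000002602.16, chromosome 7, 25757273 to 25788705) did not pass (147 ± 45.2 to 98.5 ± 18.4 CPM; log2 fold change -0.58, SE 0.220, edgeR adjusted p = 0.362; 3 of 4 Ang II libraries below every sham library). Tyro3 and the ligand genes Gas6 and Pros1 did not pass either (-0.40, -0.11 and 0.00454), nor did the angiotensin receptor gene Agtr1a (0.25). Their edgeR adjusted p lay between 0.758 and 0.995.

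**Figure D3:**
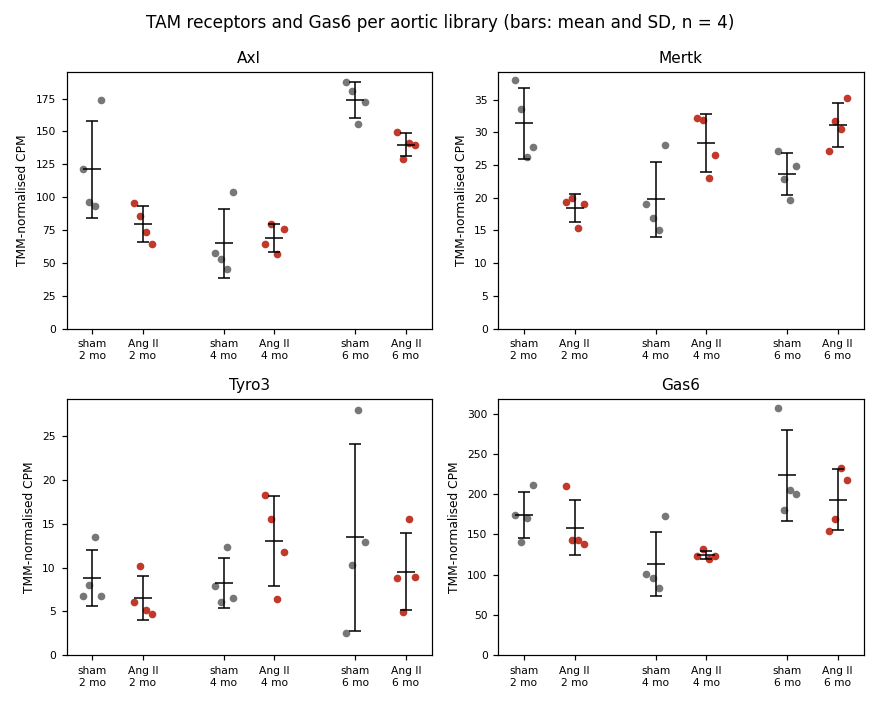
Axl, Mertk, Tyro3 and Gas6 in CPM (TMM-normalised over all 24 libraries, linear axes) by group, with points for libraries, horizontal lines for means and bars for SD (n = 4). Mertk passed the edgeR test at 2 months (adjusted p = 0.0346) and Axl at no time.

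At 2 months 297 of 16421 genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 61 higher and 236 lower in Ang II aortas, each with 4 of 4 Ang II libraries beyond every sham library. At an unadjusted p under 0.05 there were 1770 genes, and 192 of the called genes had an absolute log2 fold change of at least 1. The groups did not overlap for 1286 genes, 7.83% of those tested, where chance gives 2.86%. DESeq2 called 691 genes, limma voom with quality weights 629, and the authors' deposited table holds 745 at an adjusted p under 0.05, among them all 297 with the same sign. The count fell to 78 without sham replicate 1 and to 135, 103 and 103 without Ang II replicates 2, 3 and 4, and edgeR called 0 genes with the contractile smooth muscle score as covariate (chosen after the data were seen) or with replicate numbers as block plus an adipocyte covariate. That score holds Acta2 and Myl9 and parts the groups at 2 months, so its use as covariate takes out much of the Ang II effect by construction.

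The comparison at 4 months asks which differences were present later. Macrophage transcripts were higher in Ang II aortas, and transcripts of fatty acid synthesis and oxidative phosphorylation were lower. Cd68 rose from 10.4 ± 1.53 to 35.3 ± 4.58 CPM (log2 fold change 1.76, SE 0.140, edgeR adjusted p = 0.0134). Ms4a7, a membrane protein gene of macrophages (ENSMUSG00000024672.11, chromosome 19, 11321039 to 11336146), rose from 2.19 ± 0.542 to 9.08 ± 0.770 CPM (log2 fold change 2.04, SE 0.209, edgeR adjusted p = 0.0166). Scd1, the stearoyl-CoA desaturase of fatty acid synthesis (ENSMUSG00000037071.2, chromosome 19, 44394451 to 44407709), fell from 6179 ± 1899 to 2536 ± 354 CPM (log2 fold change -1.28, SE 0.222, edgeR adjusted p = 0.0484). Gys2, a glycogen synthase (ENSMUSG00000030244.7, chromosome 6, 142422613 to 142473109), fell from 49.7 ± 16.6 to 15.8 ± 5.27 CPM (log2 fold change -1.65, SE 0.286, edgeR adjusted p = 0.0486).

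The macrophage and monocyte list rose at 4 months with 2 of 18 members over all genes and 11 adjusted over the list alone (median 0.76; camera adjusted p = 6.42e-11, adjusted p = 0.332 with an estimated correlation). Trem2 rose by 1.55, and outside the list Wfdc17, a secreted protein gene of macrophages, rose from 3.21 ± 0.828 to 14.9 ± 3.03 CPM (edgeR adjusted p = 0.0322 and 0.0166). Hpgds, a prostaglandin D synthase, Mpeg1, a pore-forming protein of macrophages, the inhibitory receptor gene Cd300a and the leukocyte myosin gene Myo1f rose by 1.74, 1.40, 1.37 and 0.95. Uap1l1 and Renbp, which encode enzymes or enzyme-like proteins of amino sugar metabolism, rose by 0.85 and 0.82. Of 17 matrix proteases and inhibitors, 1 rose over all genes and 3 adjusted over the list alone (median 0.46; camera adjusted p = 2.16e-05, adjusted p = 0.420 with an estimated correlation). The list was not called with the adipocyte covariate (camera adjusted p = 0.0602). The member that passed was Mmp14, a membrane-bound collagenase, from 26.7 ± 3.98 to 42.5 ± 2.16 CPM (edgeR adjusted p = 0.0443). Interferon stimulated genes rose with 0 of 20 members over all genes and 1 adjusted over the list alone (median 0.36; camera adjusted p = 1.11e-06), as did cytokines and chemokines with 0 and 2 (0.74; camera adjusted p = 3.70e-04). In the same order they had adjusted p = 0.332 and 0.332 with an estimated correlation. Antigen presentation rose with 0 members passing (0.60; camera adjusted p = 2.16e-05, adjusted p = 0.591 with an estimated correlation). Summed macrophage transcripts were 621, 471, 424 and 720.3 CPM in sham and 797, 1287, 1113 and 974 CPM in Ang II replicates 1 to 4.

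**Figure D4:**
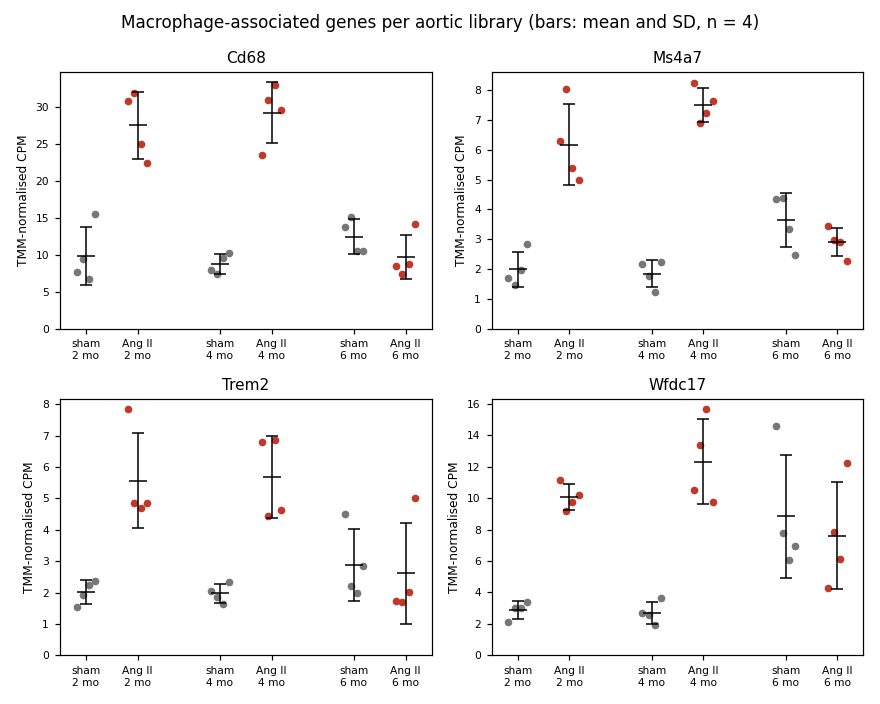
Cd68, Ms4a7, Trem2 and Wfdc17 in CPM (TMM-normalised over all 24 libraries, linear axes) by group, with points for libraries, horizontal lines for means and bars for SD (n = 4). All 4 genes passed the edgeR test at 2 and at 4 months and none at 6 months.

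The oxidative phosphorylation list fell at 4 months with 5 of 20 members over all genes and 20 adjusted over the list alone (median -0.48; camera adjusted p = 1.11e-17, adjusted p = 0.334 with an estimated correlation). Uqcrc2, a core subunit of respiratory complex III, fell from 787 ± 78.5 to 513 ± 28.03 CPM, and Sdha, the flavoprotein of succinate dehydrogenase, from 1849 ± 192 to 1257 ± 73.3 CPM (edgeR adjusted p = 0.0400 and 0.0486). The respiratory chain genes Uqcrfs1 and Ndufs1 changed by -0.61 and -0.58. Fatty acid synthesis genes fell with 2 of 16 members over all genes, Scd1 and Agpat2 (-0.68), an acyltransferase of lipid synthesis, and 8 adjusted over the list alone (median -0.68; camera adjusted p = 3.65e-07, adjusted p = 0.362 with an estimated correlation). Gpd1, a glycerol phosphate dehydrogenase, fell from 2408 ± 290.3 to 1419 ± 107 CPM, and its mitochondrial partner Gpd2 changed by -0.97 (edgeR adjusted p = 0.0375 and 0.0177). The glycogen genes Gbe1, the branching enzyme, and Ppp1r3b, a glycogen-targeting phosphatase subunit, changed by -0.86 and -1.13. The thioesterase gene Acot11, the phosphodiesterase gene Pde4a and the DNA polymerase gene Poln changed by -1.12, -0.77 and -1.31. Mpc1, a mitochondrial pyruvate carrier, and its pseudogene Mpc1-ps both fell (-0.78 and -0.80). How shared reads were counted is not given. Brown adipocyte genes fell with 0 members over all genes, and 6 lower and 1 higher of 15 adjusted over the list alone (median -0.62; camera adjusted p = 0.00139, adjusted p = 0.530 with an estimated correlation). Brown adipocyte sums were 5562, 6157, 5248 and 2562 CPM in sham and 2818, 2747, 2797 and 2925 CPM in Ang II replicates 1 to 4. Fatty acid synthesis sums were 10228, 12792, 9661 and 29444 and 7052, 7597, 5439 and 6438 CPM. Brown fat taken along may cause these falls, which was not tested.

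**Figure D5:**
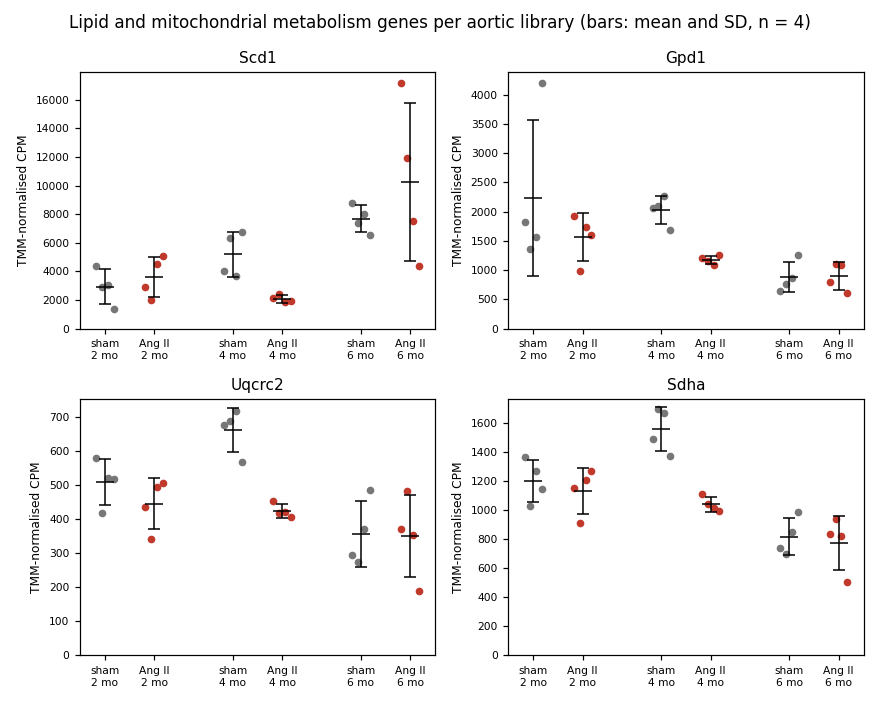
Scd1, Gpd1, Uqcrc2 and Sdha in CPM (TMM-normalised over all 24 libraries, linear axes) by group, with points for libraries, horizontal lines for means and bars for SD (n = 4). At 4 months each gene was lower in Ang II aortas, with edgeR adjusted p from 0.0375 for Gpd1 to 0.0486 for Sdha.

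Other lists moved at 4 months with 0 members passing edgeR over all genes. Erythroid genes fell (median -1.45; 5 of 6 adjusted over the list alone; camera adjusted p = 0.00105), as did contractile smooth muscle (-0.70; camera adjusted p = 0.00368), cardiac muscle (-0.81; camera adjusted p = 0.00490) and circadian clock genes (-0.15; camera adjusted p = 0.00754). Those lists had, in order, adjusted p = 0.420, 0.683, 0.712 and 0.332 with an estimated correlation. Schwann and neuronal genes rose (0.36; 3 adjusted over the list alone; camera adjusted p = 0.00490), as did fibroblast (0.16; 2 adjusted over the list alone; camera adjusted p = 0.00629), heat shock and ER stress (0.18; 1 adjusted over the list alone; camera adjusted p = 0.00754) and proliferation genes (0.98; camera adjusted p = 0.0197). In order, these had adjusted p = 0.703, 0.591, 0.334 and 0.798 with an estimated correlation. Some of these calls were lost when 1 library was left out. They were contractile smooth muscle without sham replicate 4 (camera adjusted p = 0.2503), cardiac muscle without sham replicates 1 or 4 (0.0961 and 0.111) and heat shock without sham replicate 1 (0.0597). They also were Schwann and neuronal genes without sham replicate 4 or Ang II replicate 1 (0.111 and 0.0793) and proliferation without sham replicates 2 or 3 or Ang II replicate 3 (0.130, 0.128 and 0.738). The fibroblast call was lost without sham replicate 3 (0.112) and with the adipocyte covariate (0.969). The TAM list rose with 0 of 5 members passing (0.36; camera adjusted p = 0.0348, adjusted p = 0.571 with an estimated correlation). That call was lost with the adipocyte covariate (camera adjusted p = 0.952) and in 6 of 8 leave-one-out fits. These left out sham replicates 1, 2 and 3 (0.0708, 0.0674 and 0.112) or Ang II replicates 1, 2 and 4 (0.0771, 0.0853 and 0.0528). Axl, Mertk, Tyro3, Gas6 and Pros1 had log2 fold changes of 0.11, 0.55, 0.69, 0.16 and 0.36 (edgeR adjusted p from 0.174 for Pros1 to 0.834 for Axl). Acta2, Eln, Col1a1, Col3a1 and Agtr1a did not pass (-1.03, -0.59, 0.19, 0.30 and 0.0498). Sham replicate 4 held 1057 CPM of Acta2 and the other sham replicates 219 to 233 CPM. Whether this library differs in tissue makeup or is mislabelled is not given in the sources used here, and without it edgeR called 674 genes, against 114 with it. The general adipocyte (camera adjusted p = 0.0534), immediate early, lymphatic, senescence, collagen, skeletal muscle, B cell, oxidant, T and NK cell, matricellular, endothelial, osteochondrogenic, elastic fibre, renin angiotensin aldosterone and neutrophil lists did not pass (largest adjusted p = 0.948). Signs of median, mean and test differed for the endothelial, osteochondrogenic, elastic fibre, renin angiotensin aldosterone and neutrophil lists. Hepatocyte transcripts summed to 2273 CPM in Ang II replicate 4, and airway transcripts to 6111 and 3989 CPM in Ang II replicates 2 and 4.

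At 4 months 114 of 16127 genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 23 higher and 91 lower, each with 4 of 4 Ang II libraries beyond every sham library. At an unadjusted p under 0.05 there were 2502 genes, and 16 called genes had an absolute log2 fold change of at least 1. The groups did not overlap for 1637 genes, 10.2% of those tested, where chance gives 2.86%. DESeq2 called 940 genes, limma voom 602, and the authors' deposited table holds 1028, among them all 114 with the same sign. By edgeR the count was 0, 0, 3 and 674 without sham replicates 1 to 4 and 1, 0, 0 and 0 without Ang II replicates 1 to 4. It was 0 with the adipocyte covariate, 0 with replicate numbers as block, 0 without the libraries highest in hepatocyte or airway transcripts, 21 with an airway covariate, 11 when all 24 libraries were fitted together and 40 without the low-count filter. The count rose to 319 with the contractile smooth muscle covariate and to 233 without chromosome M and ribosomal RNA genes.

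The comparison at 6 months asks which differences were left. No gene passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment among 19343 tested (smallest adjusted p = 0.294). Skeletal muscle transcripts were higher in 2 Ang II libraries. The smallest p was that of Mcf2l, a guanine nucleotide exchange factor (ENSMUSG00000031442.20, chromosome 8, 12873806 to 13020905), at 24.1 ± 1.73 to 43.9 ± 3.59 CPM (log2 fold change 0.86, SE 0.102, edgeR adjusted p = 0.294). Myh2, a myosin of fast skeletal muscle, went from 0.248 ± 0.0367 to 32.3 ± 38.02 CPM (log2 fold change 7.0, SE 1.12, edgeR adjusted p = 0.683). The other genes nearest to passing were Lrtm1 (1.56), AC109214.2 (2.17), Dysf, a membrane repair gene of muscle (0.58), Scimp, an adaptor of antigen-presenting cells (-2.01), Fbn1, fibrillin (-0.74), the adrenergic receptor gene Adra1d (-0.67), the nuclear receptor gene Nr4a3 (-0.74) and the fibroblast gene Pi16 (-0.65). Axl was at 119 ± 8.66 to 96.05 ± 6.65 CPM (log2 fold change -0.30, SE 0.109, edgeR adjusted p = 0.922; 4 of 4 Ang II libraries below every sham library) and Mertk at 0.41 (edgeR adjusted p = 0.922; 4 of 4 above). Tyro3, Gas6, Pros1, Agtr1a, Col1a1, Col3a1, Eln and Acta2 did not pass (-0.49, -0.20, -0.16, -0.29, -0.37, -0.47, -0.23 and 0.20).

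As a list, skeletal muscle rose at 6 months with 0 of 17 members over all genes and all 17 adjusted over the list alone (median 3.35; camera adjusted p = 8.19e-19, adjusted p = 0.267 with an estimated correlation). Its summed level was 3547, 4827, 25105 and 20535 CPM in Ang II and 2027, 4474, 3034 and 3171 CPM in sham replicates 1 to 4. Contractile smooth muscle rose (0.35; camera adjusted p = 2.19e-08), as did the circadian clock (0.33; 8 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.00183) and osteochondrogenic lists (0.41; 2 higher; camera adjusted p = 0.00369). These had, in order, adjusted p = 0.213, 0.313 and 0.313 with an estimated correlation. Matrix and stromal lists fell: matrix proteases (-0.30; camera adjusted p = 8.60e-05), collagens (-0.27; camera adjusted p = 8.60e-05), fibroblast (-0.22; camera adjusted p = 8.60e-05) and elastic fibre genes (-0.21; camera adjusted p = 4.38e-04). Those had adjusted p = 0.213, 0.265, 0.265 and 0.326 with an estimated correlation. Adjusted over the list alone these held 1 higher and 3 lower, 1 and 1, 0 and 1, and 0 and 1 members. Immune lists fell: macrophage (-0.28; camera adjusted p = 4.16e-04), antigen presentation (-0.38; camera adjusted p = 2.85e-05), neutrophil and mast cell (-0.52; 2 adjusted over the list alone; camera adjusted p = 3.13e-04), B cell (-0.69; camera adjusted p = 0.00249) and T and NK cell (-1.21; camera adjusted p = 0.00326). In that order these immune lists had adjusted p = 0.386, 0.430, 0.313, 0.691 and 0.691 with an estimated correlation. Without sham replicate 2 the T and NK cell list pointed the other way (camera adjusted p = 0.896). It was not called without Ang II replicates 1 or 2 (0.0676 and 0.0861) or with the adipocyte covariate (0.0642). Nor were B cells without sham replicate 2 or Ang II replicate 3 (0.684 and 0.113), elastic fibre genes without sham replicate 1 (0.0762) or the circadian list without Ang II replicate 3 (0.0502). Proliferation genes also fell (-0.54; camera adjusted p = 1.47e-05, adjusted p = 0.430 with an estimated correlation). The TAM list (-0.20; camera adjusted p = 0.531) and thymocyte list (0.10; camera adjusted p = 0.452) did not pass, nor did the remaining 17 lists. Squamous epithelium transcripts, from a list chosen after the data were seen, summed to 16.9, 12.4, 17427 and 3404 CPM in sham and 517, 121, 5872 and 4951 CPM in Ang II replicates 1 to 4 at 6 months, and one ribosomal RNA gene took 13.642% of the counts in Ang II replicate 4.

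At an unadjusted p under 0.05 there were 976 genes at 6 months, DESeq2 called 63, limma voom 0, and the authors' deposited table holds 68. The groups did not overlap for 604 genes, 3.12% of those tested, where chance gives 2.86%. In counts with changes planted, edgeR with this design found 77.3% of 4-fold and 8.96% of 2-fold changes at 6 months, against 87.9% and 49.3% at 2 months and 90.9% and 59.7% at 4 months. Leaving out any 1 of the 8 libraries gave 0 genes each time.

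Whether the Ang II effect differed between times was tested with an interaction of treatment and time. For 103 of 19218 genes it did (edgeR quasi-likelihood with Benjamini-Hochberg; 2289 genes at an unadjusted p under 0.05). Cd68 and Ms4a7 were among the genes with the smallest p. Mean levels of Cd68 in sham and Ang II aortas were 9.78 ± 3.97 and 27.2 ± 4.29 CPM at 2 months, 8.69 ± 1.28 and 29.1 ± 4.09 at 4 months, and 12.7 ± 2.48 and 9.96 ± 3.28 at 6 months (edgeR adjusted p = 0.00800). Ms4a7 showed the same course (1.97 and 6.09, 1.83 and 7.48, then 3.71 and 2.96 CPM). So did Mmp14 (32.1 and 45.02, 22.3 and 35.00, 43.1 and 31.7 CPM), Uap1l1 (14.5 and 18.6, 12.2 and 21.7, 15.3 and 12.6 CPM) and the gene of the receptor of platelet-activating factor, Ptafr (4.75 and 10.2, 4.28 and 7.94, 15.2 and 10.5 CPM). Lower in Ang II aortas at 2 months and higher at 6 months was Enah, a regulator of actin filaments (78.4 ± 9.04 and 31.04 ± 2.04, 38.00 ± 10.3 and 30.9 ± 7.29, 56.9 ± 9.71 and 74.2 ± 11.04 CPM). The same held for Dysf (50.02 and 32.8, 35.3 and 35.3, 27.01 and 40.4 CPM), Bhlhe41 (37.4 and 17.6, 42.2 and 29.9, 11.3 and 17.2 CPM) and Banp, a nuclear matrix protein gene (ENSMUSG00000025316.16, chromosome 8, 121949750 to 122029258; 16.95 and 8.53, 9.81 and 12.2, 15.2 and 16.8 CPM). Sesn2, a stress-induced inhibitor of growth signals, was higher at 2 months and lower at 6 months (8.11 and 29.6, 11.4 and 12.4, 20.9 and 14.8 CPM). The edgeR adjusted p of these 10 genes lay between 0.00770 and 0.00800. Over the 2- and 4-month libraries alone edgeR called 0 genes, and with replicate numbers as block within time 1 gene. The count was 34 without sham replicate 1 and 60 without Ang II replicate 3 at 2 months, 308 without sham replicate 4 at 4 months, 58 and 58 without sham replicates 2 and 3 and 62 and 42 without Ang II replicates 2 and 3 at 6 months. DESeq2 called 536 genes and limma voom 787.

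The genes called at 2 and at 4 months came from separate libraries, with 15858 genes tested at both. Of the higher genes, 61 and 22, 7 were shared (Cd68, Ms4a7, Trem2, Wfdc17, Hpgds, Cd300a and Heph, a ferroxidase gene named after its values were seen), where chance gives 0.0846 (one-sided Fisher's exact test, p = 1.42e-12, across genes, which are not independent). Of the lower genes, 227 and 90, 0 were shared, where chance gives 1.29 (one-sided Fisher's exact test, p = 1). At 4 months 47 of the 61 genes higher at 2 months, and 166 of the 227 lower ones, had the same sign. At 6 months the sign was the same for 13 of the 61 and 114 of 234, and for 2 of the 22 and 31 of the 91 genes called at 4 months.

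Averaged over the times, the Ang II effect passed for 1 gene, Gpt2, the mitochondrial alanine aminotransferase (ENSMUSG00000031700.11, chromosome 8, 85492576 to 85527560; log2 fold change 0.58, SE 0.0783, edgeR adjusted p = 0.00271). Its mean level was higher in Ang II than in sham aortas at each time (75.2 ± 11.02 and 118 ± 5.96, 104 ± 21.5 and 152 ± 13.8, 50.2 ± 6.28 and 73.9 ± 10.4 CPM). Axl (log2 fold change -0.27, SE 0.134, edgeR adjusted p = 0.727) did not pass, nor did Mertk, Tyro3, Gas6, Pros1, Agtr1a, Col1a1, Col3a1, Eln and Acta2 (0.0575, -0.0843, -0.0700, 0.0519, -0.0142, -0.29, -0.12, -1.18 and -1.13). The signs of Mertk, Tyro3, Gas6, Agtr1a and Col3a1 changed under some alternatives. Among the genes nearest to passing were the serpin genes Serpina3b and Serpina3c (2.18 and 0.52), Slc43a1 (0.51), Slc12a4 (-0.34), Nrtn, neurturin (-0.55), Adra1d (-0.62), Lamc3 (-0.48) and Gmppa (-0.17), with edgeR adjusted p from 0.140 to 0.193. Of 33 lists 19 passed camera, with no member passing edgeR over all genes. Macrophage genes rose (0.37; 5 of 18 adjusted over the list alone; camera adjusted p = 4.47e-10, adjusted p = 0.321 with an estimated correlation), as did immediate early genes (0.64; 11; camera adjusted p = 4.05e-09, adjusted p = 0.336 with an estimated correlation). Oxidative phosphorylation (-0.21; camera adjusted p = 4.47e-10), contractile smooth muscle (-0.60; 10 adjusted over the list alone; camera adjusted p = 4.44e-08), elastic fibre (-0.33; 13; camera adjusted p = 4.44e-08) and erythroid genes (-1.11; 6; camera adjusted p = 5.53e-08) fell. They had adjusted p = 0.336, 0.336, 0.336 and 0.321 with an estimated correlation. Signs of median, mean and test differed for the T and NK cell, lymphatic, senescence, endothelial, fibroblast, osteochondrogenic and oxidant lists.

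For the average, 19218 genes were tested by edgeR and 1326 had an unadjusted p under 0.05. DESeq2 called 58 genes and limma voom 30, and edgeR called 99 with the adipocyte covariate, 157 over the 2- and 4-month libraries alone and 0 with replicate blocks. The count rose to 2 without sham replicate 2 at 4 months, to 3 and 2 without sham replicates 1 and 2 at 6 months and to 7 without Ang II replicate 3 at 6 months.

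Sham aortas at 4 and 2 months differ in the time since infusion, with libraries of like kind. Time may still be confounded with a processing batch, which the labels do not give. Contractile sums in sham libraries were 5649 to 8879 CPM at 2 months, against 1698 to 5022 CPM in all libraries at 4 and 6 months. The contractile fall below therefore rests on the same sham libraries as the fall after Ang II at 2 months. Smooth muscle and matrix transcripts were lower at 4 months. Lmod1 and Mylk, the myosin light chain kinase, changed by -1.74 and -1.48, Actg2, gamma smooth muscle actin, by -2.25 and Col6a3 by -0.96 (edgeR adjusted p from 0.0345 for Mylk to 0.0455 for Col6a3). The contractile list fell with 5 of 20 members over all genes and 15 adjusted over the list alone (median -1.69; camera adjusted p = 1.77e-13, adjusted p = 0.223 with an estimated correlation). Collagens (-0.95; 15 of 16 adjusted over the list alone; camera adjusted p = 1.36e-12), elastic fibre (-0.81; 16 of 23; camera adjusted p = 1.92e-13) and matricellular genes (-0.93; 9 of 17; camera adjusted p = 5.97e-07) fell too. In that order the lists had adjusted p = 0.223, 0.279 and 0.223 with an estimated correlation. The TAM list fell with 0 members over all genes and 4 of 5 adjusted over the list alone (-0.62; camera adjusted p = 0.00452, adjusted p = 0.223 with an estimated correlation). T and NK cell (1.05; camera adjusted p = 5.97e-07), B cell (1.19; camera adjusted p = 6.34e-06) and oxidative phosphorylation genes (0.37; camera adjusted p = 4.58e-09) rose. In order, those had adjusted p = 0.472, 0.472 and 0.447 with an estimated correlation. General adipocyte (camera adjusted p = 8.09e-04) and erythroid lists (camera adjusted p = 7.10e-04) rose as well. Endothelial (camera adjusted p = 0.0297) and fibroblast lists (camera adjusted p = 0.00505) fell. With an estimated correlation these 4 lists had adjusted p = 0.447, 0.447, 0.597 and 0.566. The heat shock genes Hspa1a and Hspa1b changed by -2.10 and -2.09, and Prdm16 by -1.04. The largest rises were Akr1b7, an aldo-keto reductase of the adrenal cortex (6.34), and the platelet genes Tubb1, Treml1, Ppbp and Gp9 (3.96, 3.29, 3.16 and 2.77). Large falls were those of Vstm2b, Stum, Pi15 and the potassium channel gene Kcnab1 (-2.55, -2.47, -2.31 and -2.29). Adrenal cortex transcripts summed to 161, 14.1, 172 and 10.1 CPM in sham replicates 1 to 4 at 4 months, and B cell transcripts to 2735, 604, 854 and 1202 CPM there and 309, 1381, 286 and 745 CPM at 2 months.

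Between sham aortas at 4 and 2 months 115 genes passed edgeR, 9 higher and 106 lower, with 2771 at an unadjusted p under 0.05, and 20 of 32 lists passed camera. Signs of median, mean and test differed for the immediate early and circadian lists. With the 8 sham libraries of 2 and 4 months fitted alone edgeR called 1 gene. In the fit with all 12 DESeq2 called 835 genes and limma voom 824. EdgeR called 4 with the adipocyte covariate, 30 with a mean count filter and 275 with replicate numbers as block. The edgeR count was 0, 5, 63 and 7 without sham replicates 1 to 4 at 2 months, 0, 3, 1 and 621 without those at 4 months, and 51, 5, 5 and 8 without those at 6 months, which enter the fit's spread.

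Sham aortas at 6 months differ from the earlier ones in time and in kind of library at once. Of 17808 genes 11301 differed over the times in edgeR's quasi-likelihood test, 10409 at 6 against 2 months (4981 higher and 5428 lower) and 11181 at 6 against 4 months (5725 higher and 5456 lower). Transcripts of nerve were lower at 6 months. Npy, a neuropeptide of sympathetic neurons (ENSMUSG00000029819.6, chromosome 6, 49822710 to 49829507), was at 99.5 ± 34.4, 154 ± 92.1 and 0.127 ± 0.125 CPM at 2, 4 and 6 months (6 against 2 months, log2 fold change -9.48, SE 0.668, edgeR adjusted p = 1.15e-06). Hand1, a transcription factor, was at 13.99, 23.4 and 0.0210 CPM, and the neuronal gene Gap43 changed by -5.53. The Schwann and neuronal list fell with 18 of 20 members over all genes (median -4.03; camera adjusted p = 1.04e-07, adjusted p = 0.986 with an estimated correlation).

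Small RNAs without poly(A) tails were higher at 6 months, such as Scarna6 and Snord17 (12.02 and 11.78 against 2 months; edgeR adjusted p = 2.70e-07 and 1.28e-07). The signal recognition particle RNA genes Rn7s1 and Rn7s2 had groups with all libraries at 0, so no fold is given. Krt13, a keratin of squamous epithelium, was at 2069.7 ± 3284 CPM at 6 months and 0.0346 CPM at 2 months. Oxidative phosphorylation genes fell with 19 of 20 members against 2 months (-0.77; camera adjusted p = 2.60e-05) and 20 against 4 months (-1.12; camera adjusted p = 2.00e-07), among them Cox5b and Cycs (-1.92 and -1.61 against 2 months). The lists had, in order, adjusted p = 0.986 and 0.765 with an estimated correlation. General adipocyte genes fell with 14 of 20 (-0.96; camera adjusted p = 0.00345, adjusted p = 0.986 with an estimated correlation). Fabp4, a fatty acid carrier of adipocytes, was at 5482 ± 373, 8076 ± 897 and 1729 ± 308 CPM. Contractile smooth muscle genes fell against 2 months with 14 lower and 2 higher of 20 (-1.71; camera adjusted p = 0.00653), as did endothelial (-0.52; camera adjusted p = 0.0279) and heat shock genes (-0.52; camera adjusted p = 0.0279). In the same order these had adjusted p = 0.986, 0.986 and 0.986 with an estimated correlation. Macrophage genes rose with 9 of 18 (0.65; camera adjusted p = 0.0279, adjusted p = 0.986 with an estimated correlation), Adgre1 and Mrc1, the mannose receptor, by 1.96 and 1.69. Lymphatic and mesothelial genes rose (1.26; camera adjusted p = 0.0478, adjusted p = 0.986 with an estimated correlation), with the mesothelial genes Wt1 and Upk3b at 2.51 and 2.11. Against 4 months, elastic fibre (17 of 23 higher; 0.91; camera adjusted p = 0.00121), collagen (13 higher; 1.39; camera adjusted p = 0.00231) and matrix protease genes (10 higher; 0.95; camera adjusted p = 0.0192) rose, with Fbn1 and Col14a1 at 3.38 and 2.92. Those lists had adjusted p = 0.765, 0.765 and 0.765 with an estimated correlation. Axl was higher at 6 than at 4 months (64.5 and 180.2 CPM; log2 fold change 1.48, SE 0.263, edgeR adjusted p = 4.24e-04), as were Gas6 and Pros1 (1.04 and 0.44), and Agtr1a fell by 1.77 on the log2 scale. With the adipocyte covariate 759 genes differed between 6 and 2 months and 27 between 6 and 4 months.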

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

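In this part the interaction test over 2 and 4 months alone was chosen only after the results were seen. Dixon's test at its 95% critical value for 4 samples was run on 242 groups of 4 values and picked out 22 of them (9.1%), where chance picks out about 1 in 20. At 2 months, Ang II replicate 1 stood apart from the other Ang II replicates in 7 genes, among them Acta2 at 664 CPM (others 226 to 292), Myl9 at 215 (92.4 to 110.2) and Ltbp1 at 37.2 (23.0 to 25.2). Others were Ccdc42 at 1.15 (0.258 to 0.364), Gas6 at 210.1 (138 to 143), Trem2 at 7.84 (4.69 to 4.87) and Arc at 24.9 (7.88 to 9.75). Wif1 was at 0 CPM in Ang II replicate 3 (others 0.303 to 0.364). Tgfb2 was at 12.04 CPM in sham replicate 2 (15.6 to 16.2) and Tnc at 44.8 CPM in sham replicate 1 (25.8 to 27.2). At 4 months sham replicate 4 stood apart in Acta2 at 1057 CPM (219 to 233), Eln at 329 (52.6 to 60.3), Gbe1 at 191 (146 to 147), Mpc1-ps at 29.2 (19.7 to 20.7) and Mmp14 at 27.5 (20.4 to 21.2). Gys2 was at 63.2 CPM in sham replicate 1 (32.6 to 36.7), Mmp14 at 32.2 CPM in Ang II replicate 1 (35.7 to 36.4) and Uqcrfs1 at 387 CPM in Ang II replicate 4 (422 to 424). The share of counts on one ribosomal RNA gene was 0.19% in sham replicate 4 at 2 months (others 0.104% to 0.117%), 0.597% in sham replicate 1 at 4 months (0.155% to 0.223%), 0.333% in sham replicate 2 at 6 months (0.072% to 0.076%) and 13.642% in Ang II replicate 4 at 6 months (0.023% to 0.197%).

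For 10 named genes edgeR's interaction test with Benjamini-Hochberg adjustment passed. The adjusted p was 0.00770 for Banp, 0.00770 for Ms4a7, 0.00770 for Bhlhe41, 0.00770 for Uap1l1, 0.00770 for Sesn2, 0.00770 for Dysf, 0.00770 for Mmp14, 0.00796 for Ptafr, 0.00796 for Enah and 0.00800 for Cd68. Their levels at 6 months come from libraries of another kind, and edgeR called 0 genes for the interaction over 2 and 4 months alone.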

How the results depend on the processing

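Fits with the smooth muscle, airway or squamous covariate, without the 6-month libraries, without chromosome M and ribosomal RNA genes, and without the libraries highest in airway, hepatocyte, squamous or ribosomal RNA transcripts were chosen after the results were seen. Counts refer to edgeR at an adjusted p under 0.05 unless another tool is named, and the cause was not tested for any change except where a stricter threshold or fewer libraries made it. Of the 1056 alternative values of the 48 called genes named at 2 months, 704 kept direction and call, 339 lost the call and 13 changed sign. At 4 months 225 of 594 values for 27 genes kept both and 369 lost the call. Of the interaction, 318 of 350 values stayed past the threshold. For sham aortas at 4 against 2, 6 against 2 and 6 against 4 months, 153 of 336, 1860 of 1974 and 1929 of 2079 kept both. For the called lists at 2, 4 and 6 months, on average and in sham 4 against 2 months, 183 of 215, 166 of 202, 146 of 168, 455 of 529 and 273 of 319 values kept both. Fits with DESeq2 size factors or without chromosome M and ribosomal RNA genes shifted the median of all genes by at most 0.0672 (log2). The labels do not say whether replicate numbers pair the libraries. The correlation of Ang II and sham libraries with the same number ran from -0.29 to 0.44 at 2, -0.19 to 0.33 at 4 and -0.17 to 0.51 at 6 months. Without chromosome M and ribosomal RNA 12.61 to 35.1 (in 1e6) counts per library were left at 6 and 16.69 to 22.35 at 4 months. The common biological coefficient of variation of the main fits, which held those genes, was 0.369 at 6 and 0.290 at 4 months. What depth limits in the Ang II comparisons was not tested.

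Counts moved by over 1.5 times as follows. At 2 months (297) they were 691 with DESeq2, 629 with limma voom, 192 with a log2 fold change of at least 1 (fewer genes by construction), and 0 with the replicate block plus adipocyte covariate or with the smooth muscle covariate. At 4 months (114) they were 940 with DESeq2, 602 with limma voom, 40 without the low-count filter, 68 with a mean count of at least 5, and 16 with a log2 fold change of at least 1. They were 11 with all 24 libraries, 21 with the airway covariate, 319 with the smooth muscle covariate and 233 without chromosome M and ribosomal RNA genes. The count was 0 with the adipocyte covariate, the replicate block, both, or without the hepatocyte-high and airway-high libraries. At 6 months (0) DESeq2 gave 63 and each of the other fits 0, the squamous covariate and replicate block included. The interaction (103) gave 536 with DESeq2, 787 with limma voom, 1 with the replicate block, 5 with the adipocyte covariate added and 0 at 2 and 4 months only. The average (1) gave 58 with DESeq2, 30 with limma voom, 99 with the adipocyte covariate, 157 at 2 and 4 months only, and 0 with a log2 fold change of at least 1 or either block. Sham over time (11301) gave 749 with the adipocyte covariate, 5426 with a log2 fold change of at least 1 and 1 at 2 and 4 months only. Sham 4 against 2 months (115) gave 835 with DESeq2, 824 with limma voom, 30 with a mean count of at least 5, 4 with the adipocyte covariate, 75 with a log2 fold change of at least 1 and 275 with the block. Sham 6 against 2 months (10409) gave 759 and 5133, and 6 against 4 months (11181) 27 and 6032, with the adipocyte covariate and with a log2 fold change of at least 1. List counts at 2, 4 and 6 months, on average and in sham 4 against 2 months (18, 17, 14, 19 and 20) were 0 with an estimated correlation.

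Leaving out 1 library gave 78 (without sham replicate 1) to 255 genes at 2 months, 0 to 674 (without sham replicate 4) at 4 months and 0 at 6 months. It gave 34 (without sham replicate 1 at 2 months) to 308 (without sham replicate 4 at 4 months) for the interaction, 1 to 7 (without Ang II replicate 3 at 6 months) for the average and 10414 to 11884 for sham over time. For sham 4 against 2, 6 against 2 and 6 against 4 months it gave 0 to 621 (without sham replicate 4 at 4 months), 9657 to 10752 and 10526 to 11870. For lists it gave 14 to 24, 14 to 20, 12 to 21, 14 to 20 and 15 to 20.

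Log2 fold changes that changed sign are given with their new value, and the cause was not tested. With the smooth muscle covariate, whose score holds Acta2 and Myl9 and parts the groups at 2 months, they were Acta2 1.27, Agtr1a -0.98, Axl 1.23, Bgn 0.0836, Ccdc42 2.33, Ccl8 -0.95, Col1a1 0.43, Eln 0.66, Gas6 1.47, Ltbp1 0.13, Ltbp4 0.21, Myl9 0.55, Ppef1 1.0, Prdm16 0.0533, Pros1 -0.10, Scube3 0.64, Sost 1.09 and Wnt16 0.36 at 2 months, and Acta2 0.0395, Agtr1a -0.0919 and Eln 0.74 at 4 months. With the adipocyte covariate they were Axl -0.35, Col1a1 -0.32, Col3a1 -0.0576 and Gas6 -0.16 at 4 months, Ccl11 0.33, Cd80 -0.13, Csf3r -0.37, Cxcl12 0.11 and Runx2 -0.25 for sham 6 against 2 months, and Ccl11 0.44 for 6 against 4 months. With the replicate block added, they were Gas6 0.0165 and Tyro3 0.31 at 2 months, Agtr1a -0.13, Axl -0.26, Col1a1 -0.14 and Gas6 -0.13 at 4 months, and Tyro3 0.0508 on average. With limma voom they were Pros1 -0.0738 at 2 months, Agtr1a -0.0399 and Eln 0.24 at 4 months, and Agtr1a 0.00105, Col3a1 0.00206 and Gas6 1.25e-04 on average. Pros1 at 2 months was -0.00387 with DESeq2 size factors, -0.00540 with DESeq2, -0.0212 with all 24 libraries and -0.0139 without chromosome M and ribosomal RNA genes, and Agtr1a on average 0.00275 and 0.00222 with the first 2 of these. At 2 and 4 months only, the averages were Agtr1a 0.14, Col3a1 0.0733, Gas6 0.0172, Mertk -0.11 and Tyro3 0.14. Without the hepatocyte-high and airway-high libraries Axl was -0.10 at 4 months, and without those highest in ribosomal RNA or squamous transcripts Tyro3 was 0.18 at 6 months.

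Leaving out 1 library turned some signs. Pros1 at 2 months (-0.0355 to 0.0477 over the leave-one-out fits) turned without sham replicates 2 or 4 or Ang II replicate 4. At 4 months Agtr1a (-0.17 to 0.30) turned without sham replicates 2 or 4 or Ang II replicate 1. Eln (-0.84 to 0.56) turned without sham replicate 4, and Axl (-0.0225 to 0.43) without sham replicate 3. At 6 months Tyro3 (-0.84 to 0.16) turned without sham replicate 3, and the T and NK cell list (adjusted p from 1.44e-05 to 0.896) without sham replicate 2. On average Agtr1a (-0.0824 to 0.0602) turned without any 1 of 11 libraries (Ang II replicates 1 or 3 at 2 months, sham 1 or 3 and Ang II 2 or 3 at 4 months, sham 1 or 4 and Ang II 1, 3 or 4 at 6 months), Gas6 (-0.12 to 0.00135) without sham replicate 1 at 6 months and Mertk (-0.00113 to 0.13) without sham replicate 3 at 4 months. Tyro3 (-0.18 to 0.13) turned on average without sham replicate 3 at 2 or 6 months or Ang II replicate 2 at 6 months. No gene that turned in these leave-one-out fits had passed the test.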

Other observations

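Chosen only after results were seen were the airway covariate test, the macrophage tests against other cell types and their division by time, the tissue lists, the squamous covariate, the ratio outside the contractile list, the fit of 2 and 4 months alone and the doubling of the splits drawn for the interaction and the average. Sums of genes of neighbouring organs differed between libraries. Airway genes summed to 9327 CPM in sham replicate 3 at 2 months and to 7145 CPM in sham replicate 2 at 6 months, and ranged down to 2.57 CPM in sham replicate 2 at 2 months. Hepatocyte genes summed to 2273 CPM in Ang II replicate 4 and 167 CPM in Ang II replicate 3 at 4 months. Adrenal cortex genes reached 172 CPM in sham replicate 3 at 4 months. Kidney tubule genes summed to 828 to 4078 CPM at 2 and 4 months and 334 to 915 CPM at 6 months. Cartilage genes reached 49.3 CPM in Ang II replicate 1 at 6 months. Squamous epithelium genes summed to 0.868 to 7.09 CPM at 2 and 4 months.

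The fall of smooth muscle and elastic fibre genes at 2 months was weighed first, as a hypothesis that the Ang II homogenates held a smaller share of vessel wall. From its slope on the contractile score within the groups at 4 and 6 months, each of the 236 lower genes was given a predicted fall at 2 months. The median prediction was a log2 fold change of -0.93 against an observed -1.17, a ratio of 0.795 (interval 0.712 to 0.845 from a bootstrap over genes, which are not independent), and the interval holds the bound of 0.75 set for it. A smaller share and a lower level of these transcripts per smooth muscle cell cannot be told apart, since both lower the score that enters the prediction, and 0.781 was the ratio for the 224 genes outside the contractile list. The high sham level at 2 months stays open too. Of the 236 genes, 188 were still lower with the airway score as covariate, and the median of the 236 was -1.17 before and after. Airway sums overlapped, at 2.57 to 9327 CPM in sham and 12.99 to 2433 CPM in Ang II libraries, so the covariate could take out little and decides nothing. Sham replicates 1 and 2, with airway sums of 16.4 and 2.57 CPM, had contractile sums of 7624 and 6048 CPM. Both sums lay above every Ang II library (2089.7 to 3344 CPM), which argues against airway tissue in a sham library for the contractile transcripts.

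The rise of macrophage genes at 2 and 4 months was weighed against 2 kinds of tissue mix. With the B cell score as covariate the 7 genes higher at both times kept a median share of 0.995 of their log2 fold change (0.883 to 1.05). At 2 months the median share was 0.994, but only 1 of the 7 genes was still called there. B cell sums at 2 months overlapped in part, at 286 to 1381 CPM in sham and 624 to 2754 CPM in Ang II libraries. The estimates hardly moved but most calls were lost, so lymphoid tissue in the Ang II libraries is not decided at 2 months. At 4 months, with the same loss of 1 residual degree of freedom, 7 of the 7 were still called. B cell sums at 4 months overlapped, at 604 to 2735 CPM in sham and 768 to 2331 CPM in Ang II libraries, so the covariate could take out little and decides nothing there. A smaller share of smooth muscle would raise all other cell types alike: at 4 months the macrophage median exceeded that of the other types by 0.64 (lower quartile 0.43 against their upper quartile of 0.33), which argues against it. At 2 months the difference was 0.52 and these quartiles overlapped (0.23 and 0.24), so this explanation cannot be told apart from a change in macrophages there. More macrophages or more transcripts per macrophage after Ang II stay open and were not tested.

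The contrast of 6-month with earlier sham libraries was weighed last. Capture of RNA without poly(A) tails is consistent with the 47 replication-dependent histone genes, whose median log2 fold change was 6.05 (quartiles 3.43 to 7.29, 42 higher and 3 lower), against -0.0623 for 15020 protein-coding genes. Of 30 snoRNA genes 29 were higher, as were 9 of 10 scaRNA and 12 of 13 snRNA genes. Deeper sequencing is argued against, since 9848 genes were still called (10409 before) after thinning to a total of 19.98 (in 1e6). The age of the mice is confounded with the kind of library and stays open. Sums of nerve and fat transcripts differed as well. In sham libraries Schwann and neuronal genes summed to 835 to 2185 CPM at 2 and 4 months and 206 to 238 CPM at 6 months. General adipocyte genes summed to 34920 to 49864 CPM and 15955 to 21995 CPM. Whether the tissue taken along with the aorta differed at 6 months was not tested and cannot be told apart from age or kind of library.

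Other splits of the same libraries were fitted to ask whether chance gives as many calls, with a bound of 0.05 on the share of splits. A share of 1 of 35 is the smallest that 8 libraries can give. Shares were not adjusted over the comparisons, so none excludes chance by itself. For genes at 2 months the share lay under the bound: 1 of 35 splits, the real one, gave as many as 297, with 75 the highest of the others. The share was also 1 of 35 at 4 months (114 against 1), but leaving out 1 library there gave 0 to 674 genes, so that result is not firm. Sham 6 against 2 months (10409 against 226) and 6 against 4 months (11181 against 0) had 1 of 35 too. Sham over time had 1 of 100 (11301 against 10678, which points to the structure of the samples by time). For sham 4 against 2 months the 12-library fit gave 1 of 35 (115 against 3). That holds for that fit only, since edgeR called 1 gene with the 8 libraries of 2 and 4 months alone. At 6 months the real count was 0, which all 35 of 35 splits reach, so the splits decide nothing there. The highest of the other splits gave 319 genes. That split set replicates 3 and 4 of both groups against replicates 1 and 2 of both and points to a structure of the samples, along which squamous epithelium transcripts ran. With the squamous score as covariate, as with the replicate block, edgeR called 0 genes, with 976 at an unadjusted p under 0.05 in the plain fit. For the interaction 3 of 100 splits gave as many as 103 (highest other 198). These splits shuffle treatment within each time, which takes away the average Ang II effect as well, so they do not test the interaction alone. For the average 6 of 100 gave at least 1 (highest other 79, which points to a structure of the samples), so chance cannot be excluded. In the first 50 splits drawn these numbers were 3 and 2, on the other side of 0.05 for both, so neither comparison is decided. For the number of lists on average, 2 of 100 splits gave at least 19 (highest other 21). That share lies under 0.05, but the splits drawn were doubled after results were seen. No list on average passed with the estimated correlation or with fry, so the share does not exclude chance. Chance cannot be excluded either at 2 months (3 of 35; 18 against 18), 4 months (7 of 35; 17 against 22) and 6 months (6 of 35; 14 against 19), nor for sham 4 against 2 months (3 of 35; 20 against 23), 6 against 2 months (25 of 35; 8 against 17) and 6 against 4 months (28 of 35; 8 against 20).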
